A study of Mus musculus with 4 samples.

How the data were processed

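RNA-seq gene counts of mouse bone marrow-derived macrophages were analysed. Per the labels' protocols, bone marrow cells were grown for 7 days with conditioned medium of L929 fibroblasts, which secrete macrophage colony-stimulating factor, and were then transfected for 24 h with a negative-control mimic or a miR-204-3p mimic. A mimic is a synthetic double-stranded RNA that is processed like a natural microRNA duplex. Each group had 2 libraries. Libraries were made from total RNA with the NEBNext Ultra RNA kit, per the labels' protocols. The submitters' processing notes name the aligner HISAT2 and the mouse assembly mm10, while the HISAT2 version, the counting program and the strand setting were not given in the sources used here. The labels do not say that the 2 libraries of a group came from separate animals or cultures, so p-values measure only the spread between these samples, which may be technical.

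The table deposited by the authors holds raw counts per gene as whole numbers, per the file headers, for 54532 genes with their symbol, biotype and coordinates. No column was left unused and no row lacked a gene. Of these gene identifiers, 54495 were also in GENCODE vM21, which annotates GRCm38, the assembly of mm10, and 98.3% of the shared ones had the same chromosome, start and end. Counting was not stated to use strand, so reads of a gene and of an overlapping or antisense gene could be mixed.

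Total counts were 16446212 and 15899235 in the control libraries and 16837826 and 16295262 in the miR-204-3p mimic libraries. A count of 0 in a library allowed up to 3 counts, which is 0.178 to 0.189 CPM, which are counts divided by total counts times 1e6. These floors, and the 95% Poisson intervals of ratios for genes with 1 to 3 counts in a group, cover counting error only, since reads copied by PCR are not independent molecules.

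Differential expression was tested in R 4.3.3 with the quasi-likelihood F test of edgeR 4.0.16 (glmQLFit and glmQLFTest, two-sided), with trimmed mean of M-values (TMM) factors, the low-count filter filterByExpr by group, and Benjamini-Hochberg adjustment at 0.05 over all tested genes. The model held the group only. CPM values were scaled with the TMM factors, which were 0.878 and 0.886 for the control libraries and 1.14 and 1.13 for the mimic libraries. Standard errors of log2 fold changes were derived from the F statistic. Before the data were examined, 37 gene lists were fixed for macrophage functions, metabolism, stress, the small RNA pathway and 7 other cell types. The 33 lists with at least 5 tested members were tested with camera of limma 3.58.1 at a preset correlation of 0.01 between genes, with Benjamini-Hochberg adjustment over the lists, and again with an estimated correlation. Camera compares a list with all other tested genes. With an estimated correlation it uses only the few residual degrees of freedom of 4 libraries, which makes any call unlikely. Some genes stand in more than 1 list, such as Bst2, which was listed as interferon-stimulated and as a dendritic cell marker.

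Genes named in the text were chosen by a rule fixed before the data were examined. It takes the 10 genes with the largest positive and the 10 with the largest negative log2 fold change among those past the threshold, with an average log2 CPM of at least 3, groups that did not overlap and a symbol that is not a model name. It adds up to 3 members per list and direction with the lowest p, a fixed set of 10 genes (Adgre1, Csf1r, Trpm3, Ago2, Dicer1, Tlr4, Gnb4, Tnf, Il1b and Il6), and the 5 lower genes of lowest p with an 8mer site. Some genes that the rule gives are left out of the text for length, and some are not reported here. Genes outside the rule are said to be so where they appear.

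Seed sites were sought in the longest annotated 3′ UTR of tested protein-coding genes, from the GENCODE vM21 annotation and transcripts, for 11267 of 11352 genes. The 7mer-m8 site TTCCCAG is the DNA complement of bases 2 to 8 of miR-204-3p, and the 8mer TTCCCAGA adds an A. The median log2 fold change of genes with the site minus that of genes without was ranked among the differences of 419 other 7-mers of the same base composition (one-sided, lower, threshold the lowest 5%). An interval came from 2000 bootstrap draws of genes, which are not independent replicates. Shared sequence was measured as the percentage of a gene's 50-mers, over its annotated transcripts, that also occur in transcripts of another gene.

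The tests were first run on simulated data. With counts drawn from the real means, library sizes and dispersion for 12849 tested genes, edgeR recovered 13 of 50 genes changed 1.5-fold, 39 of 50 changed 2-fold, 46 of 50 changed 4-fold and 49 of 50 changed 8-fold, and 11 of its 158 calls were unchanged genes. Camera ranked the shifted list at 1 and called 1 of 99 random lists. Few genes were changed, as many up as down, and genes were drawn independently. The simulation therefore did not test TMM scaling under a change as broad as in the data, or camera with correlated genes. A simulated shift of −0.20 in genes with the seed site ranked 3 lowest among the site and its 419 controls. With no shift the simulated difference was −0.017, while the controls had a median difference of 0.10 in the data. The simulated fold changes thus lacked this offset. The rank therefore does not show how small a shift the seed-site test could find in the data.

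Alternatives fixed before the data were examined were DESeq2 1.42.0, size factors of the RLE type, library size alone, no filter, a stricter filter of 50 counts in 2 libraries, protein-coding genes alone, a robust fit, an adjusted p of 0.01, edgeR glmTreat against 1.5-fold, the replicate number as a block, each library left out, fry in place of camera, and other seed sites and gene subsets. Gene-length offsets, library size alone for the lists, and the 8mer within deciles of UTR length were added after seeing the data. A planned analysis of FPKM was not run because the table holds counts alone. Tables and plots were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.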

Results

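Gene expression was measured by RNA-seq in mouse bone marrow-derived macrophages transfected for 24 h with a control mimic (2 libraries) or a miR-204-3p mimic (2 libraries). The design asks which transcripts differ when these cells receive a mimic of miR-204-3p, a microRNA from the 3′ arm of the miR-204 hairpin. The level of miR-204-3p after transfection was not examined here. Total counts lay between 15899235 and 16837826 per library, and 13186 genes were tested. Log2 CPM values correlated across genes at Pearson r = 0.987 between the control libraries and 0.989 between the mimic libraries, against 0.871 to 0.885 between groups. The 20 most abundant genes of a library held 14.7% and 14.3% of counts in the control libraries and 8.71% and 9.41% in the mimic libraries, and 16984 and 16720 against 19264 and 19141 genes had at least 1 count. Below, ± is the SD over 2 libraries after a CPM value and the standard error after a log2 fold change, which is always miR-204-3p mimic over control mimic.

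In macrophages with the miR-204-3p mimic, most interferon-stimulated genes were higher, and most genes of macrophage identity, of glycolysis and hypoxia, and of cytosolic ribosomal proteins were lower. Lcn2 (ENSMUSG00000026822, mm10 chromosome 2, 32384633 to 32388252, minus strand), which encodes the iron-siderophore-binding protein lipocalin 2, rose from 4.75 ± 1.62 to 1126 ± 189 CPM, and Oasl2, an interferon-induced 2′-5′ oligoadenylate synthetase-like gene, from 0.663 ± 0.435 to 181 ± 8.9 CPM. Csf1r (ENSMUSG00000024621, chromosome 18, 61105572 to 61132149, plus strand), the receptor for macrophage colony-stimulating factor, fell 14.6-fold, from 731 ± 57.5 to 50 ± 2.73 CPM, and F10, which encodes coagulation factor X, fell from 215 ± 6.34 to 0.875 ± 0.234 CPM. Across the transcriptome 8022 genes passed the threshold (edgeR quasi-likelihood test with Benjamini-Hochberg adjustment), 4101 higher and 3921 lower, which is 60.8% of the tested genes. At least 2-fold differences were found for 2044 higher and 2129 lower genes, and at least 4-fold for 803 and 736. The groups did not overlap for 80.7% of tested genes, where chance gives 33.3% for 2 libraries against 2. Scaling by library size alone moved the median log2 fold change of all genes from 0.04 to 0.40 and the share of higher genes among the changed ones from 51.1% to 71.0% (6151 higher and 2513 lower), so directions are relative to the TMM scaling. Against a 1.5-fold minimum, 4470 genes passed.

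**Figure D1:**
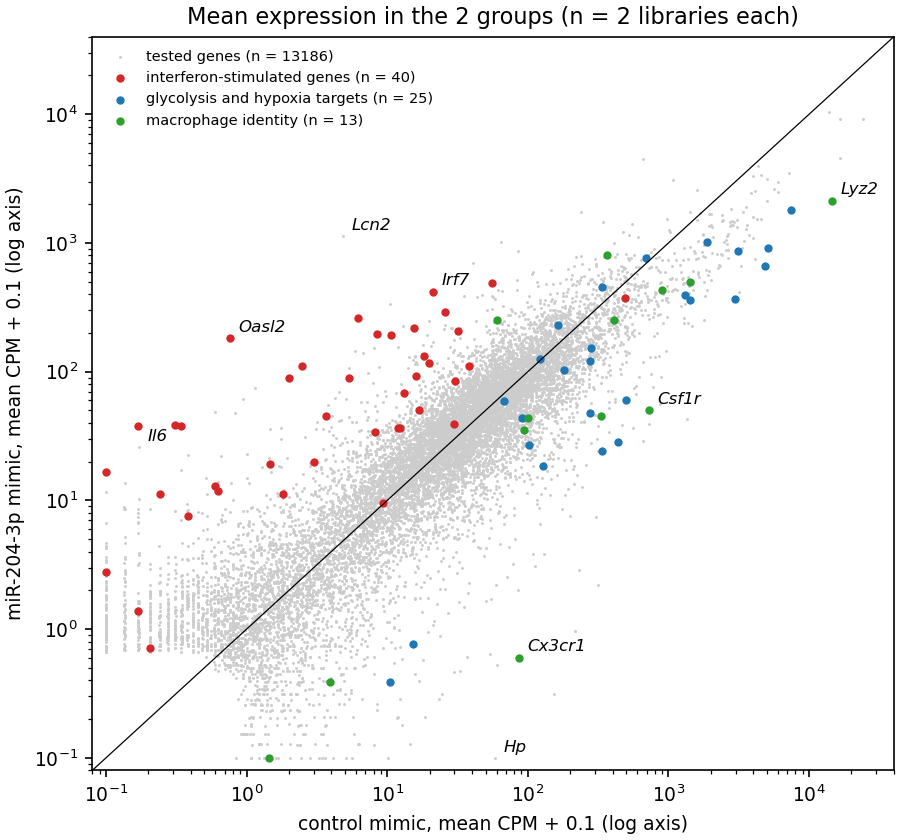
Mean CPM plus 0.1 of the 13186 tested genes in control mimic libraries (x axis, log scale) and miR-204-3p mimic libraries (y axis, log scale), each point a gene and each mean over 2 libraries, with 3 gene lists coloured and the diagonal marking equal values. Interferon-stimulated genes lie mostly above the diagonal, as Oasl2 at 0.663 against 181 CPM, and most glycolysis and macrophage identity genes below it, as Csf1r at 731 against 50 CPM.

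The other genes with the largest positive changes were Ifit3, Ifit1, Il6, Cmpk2, Rsad2, Mamdc2, Gbp9 and Apol9b. Ifit3 had 0 counts in the control libraries and 627 in the mimic libraries, at least 159-fold higher against a floor of 3 counts over the group. Ifit1, which encodes a sensor of viral RNA ends, had 2 counts against 1416 (ratio 537, counting interval 148 to 4441), and the cytokine gene Il6 had 2 against 964 (ratio 366, interval 101 to 3025). All control counts of Ifit1 and Il6 lay in 1 library each, so that their fitted log2 fold changes of 8.92 and 8.37 became 12.34 (Ifit1) and 7.42 (Il6) without control replicate 1, and 8.0 (Ifit1) and 11.80 (Il6) without control replicate 2. Cmpk2 rose by 7.47 ± 0.32 on the log2 scale, Mamdc2 by 6.62 ± 0.26 and Apol9b by 6.18 ± 0.26. The antiviral gene Rsad2 rose from 0.244 ± 0.145 to 37.6 ± 1.61 CPM and the guanylate-binding protein gene Gbp9 from 0.283 ± 0.203 to 22.5 ± 3.88 CPM. The largest negative changes, besides F10, were those of Hp, Prtn3, Cx3cr1, Ccl24, Selenbp1, Igf1, Myh14, Asb10 and Cbr2. Hp, which encodes the haemoglobin-binding protein haptoglobin, went from 1670 counts to 0, at least 734-fold lower. Prtn3, a serine protease of myeloid granules, fell from 154 ± 28.6 to 0.211 ± 0.144 CPM, the fractalkine receptor gene Cx3cr1 from 87.1 ± 16.2 to 0.502 ± 0.247 CPM, and the growth factor gene Igf1 from 60.0 ± 1.78 to 0.430 ± 0.241 CPM. Selenbp1 fell by 7.22 on the log2 scale, Ccl24 by 7.33 and Cbr2 by 6.62. Myh14 fell from 23.2 ± 7.7 to 0.185 ± 0.107 CPM and Asb10 from 24.6 ± 6.38 to 0.216 ± 0.158 CPM. Ifit3 shared 51.2% of its 50-mers with Ifit3b, Apol9b 52.3% with Apol9a, Selenbp1 46.3% with Selenbp2 and Cbr2 12.1% with a gene model, so the split of reads between these copies is uncertain. Fitted log2 fold changes of genes with few counts in a group depended on single libraries. Without control replicate 1, that of Oasl2 went from 8.07 to 8.95, of Rsad2 from 7.21 to 7.96 and of Gbp9 from 6.29 to 5.68, and without control replicate 2 that of Gbp9 to 7.26. Without mimic replicate 1, Prtn3 went from −9.45 to −10.37, Cx3cr1 from −7.41 to −8.02, Myh14 from −6.90 to −7.63 and Asb10 from −6.80 to −6.20, and without mimic replicate 2 Igf1 went from −7.11 to −7.83 and Asb10 to −7.80.

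**Figure D2:**
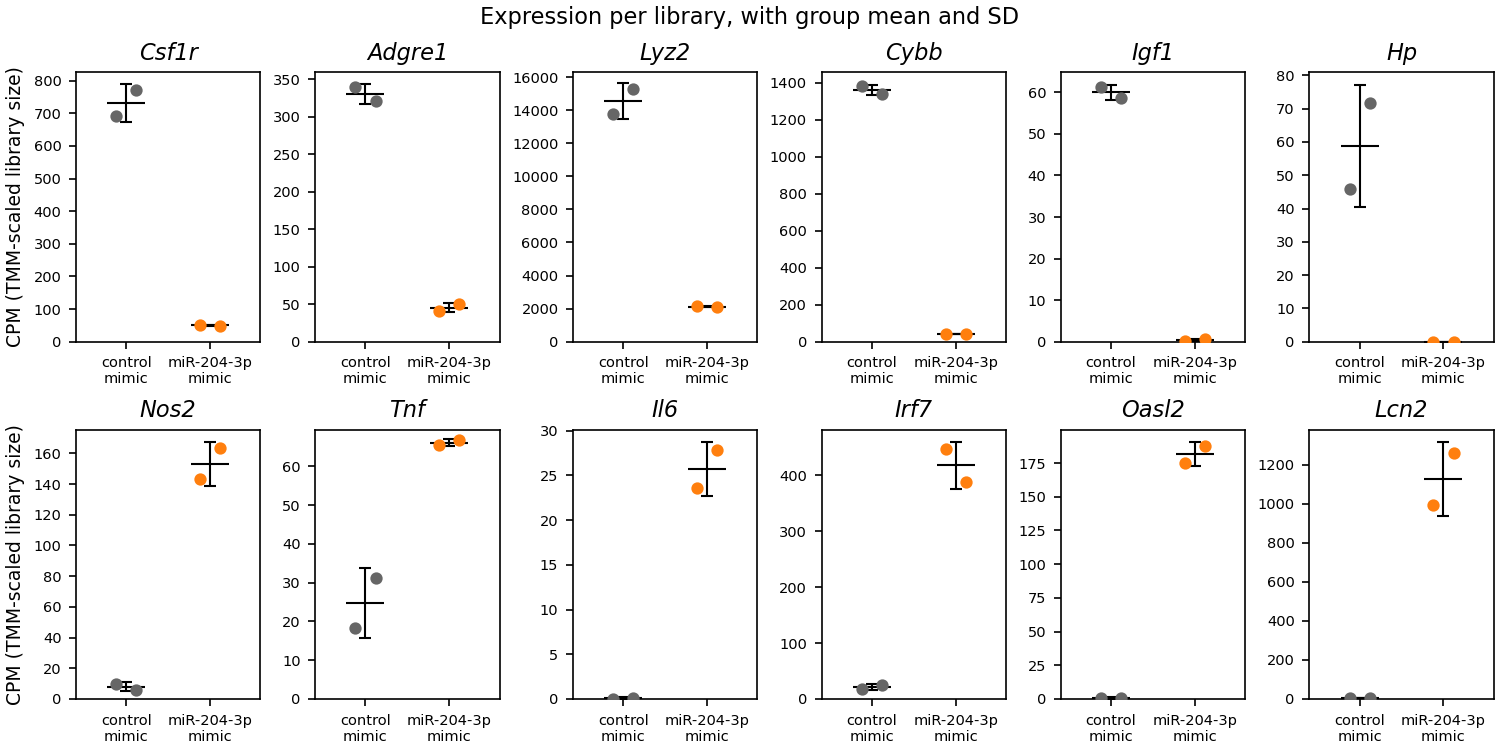
CPM (y axis, linear from 0, scaled by TMM-adjusted library size) of 12 genes in each library, with the horizontal bar at the group mean and the error bar at the SD over 2 libraries. The libraries of the 2 groups do not overlap for any of the 12 genes, and Csf1r, for example, lies near 731 CPM in the control and near 50 CPM in the miR-204-3p mimic libraries.

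Interferon-stimulated genes rose together. Of 40 tested members 37 rose, 1 fell and 2 did not pass, with a median log2 fold change of 3.73, and 38 rose and 1 fell adjusted over the list alone. Ifi44 rose by 5.44 ± 0.18, Usp18, which encodes a protease that removes ISG15, by 4.56 ± 0.16, and Irf7, which encodes a transcription factor of interferon genes, by 4.32 ± 0.18. Bst2, which encodes the virion tether tetherin, was the member that fell (490 ± 48.2 to 375 ± 32.3 CPM, edgeR adjusted p = 0.019), and this call was lost with library size alone (log2 fold change −0.02), without control replicate 1 (−0.29) and without mimic replicate 2 (−0.32), and the sign turned with gene-length offsets (0.12). Camera placed the list above other genes (adjusted p = 7.2e-44), with adjusted p = 0.12 with an estimated correlation. No list passed with an estimated correlation. Lists with an estimated correlation below 0 lost their call too, such as interferon-stimulated genes (−0.021) and glycolysis and hypoxia targets (−0.029). The few residual degrees of freedom of 4 libraries limit this version of the test, so its losses cannot be put down to correlation alone. Counts per list were the same adjusted over the list alone in 31 of the 37 lists.

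Inflammatory cytokines and mediators rose as a group, 9 higher and 2 lower of 14, with a median of 1.12. The inducible nitric oxide synthase gene Nos2 rose from 7.94 ± 2.79 to 153 ± 14.2 CPM, Il23a, a subunit of interleukin 23, from 1.37 ± 0.125 to 36.1 ± 2.1 CPM, and Tnf from 24.8 ± 9.12 to 66.1 ± 0.869 CPM. Il1b, at 2.05 ± 1.13 against 0.646 ± 0.398 CPM, fell (edgeR adjusted p = 0.018), as did Il27 (adjusted p = 0.034). Neither call held with DESeq2, with library size alone, without control replicate 2 (Il1b log2 fold change −0.96, Il27 −1.27) or without mimic replicate 1 (−1.13 and −0.84). That of Il27 was also lost without control replicate 1 (−1.30) and with gene-length offsets (−0.82), and without mimic replicate 2 the values were −2.48 for Il1b and −1.91 for Il27. The list was called by camera (adjusted p = 5.8e-05), with adjusted p = 0.32 with an estimated correlation. Genes of the NF-kB pathway and its feedback were higher in 12 and lower in 1 of 20 cases, with Traf1 up by 2.73 ± 0.24, Nfkbiz by 1.76 ± 0.16 and Nfkb1 by 1.22 ± 0.14, while the kinase gene Ikbke fell by 1.61. Camera called this list (adjusted p = 0.020), with adjusted p = 0.63 with an estimated correlation, and not without control replicate 1 (adjusted p = 0.071, median 0.28 against 0.48, which was 0.85 with library size alone), and fry did not call it (adjusted p = 0.070). Chemokines went both ways, 7 higher and 4 lower of 12 (camera adjusted p = 0.25). The neutrophil attractant Cxcl2 rose by 3.76 ± 0.18, Ccl3 by 2.28 ± 0.14 and Ccl7 by 3.21 ± 0.26, and Cxcl14 fell by 3.78 and Ccl6 by 3.77.

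Toll-like receptor genes and their adaptors were split, 10 higher and 11 lower of 27, and the list did not stand apart (camera adjusted p = 0.69). Tlr3, the receptor for double-stranded RNA, rose from 4.11 ± 0.518 to 14.2 ± 2.91 CPM and Tlr4, the lipopolysaccharide receptor, from 45.2 ± 10.3 to 71.5 ± 15.2 CPM. Tlr13, a receptor for bacterial ribosomal RNA, fell from 220 ± 21.9 to 26.0 ± 3.46 CPM, Tlr7, the receptor for single-stranded RNA, from 107 ± 1.61 to 23.8 ± 6.09 CPM, and Unc93b1, which carries nucleic acid-sensing receptors to endosomes, from 546 ± 38.3 to 196 ± 2.73 CPM. Among genes of MHC class I presentation 11 rose and 2 fell of 17 (median 0.93), with Nlrc5, the transactivator of this pathway, up by 1.94 ± 0.14 and Tapbpl by 1.90 ± 0.15, and the immunoproteasome gene Psmb8 down by 0.70. The other lower gene, H2-T22, lost its call with library size alone (log2 fold change −0.03), without control replicate 1 (−0.27) and without mimic replicate 2 (−0.36). Camera called the list (adjusted p = 0.0021), with adjusted p = 0.33 with an estimated correlation. Of 9 tested MHC class II presentation genes 4 rose and 4 fell (camera adjusted p = 0.68). The costimulatory receptors Cd40, Cd86 and Cd80 rose by 2.68 ± 0.16, 1.34 ± 0.16 and 0.84 ± 0.14, and Ifi30 and Ctss, which encode lysosomal proteins of antigen processing, fell by 2.04 and 1.32.

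Macrophage identity genes fell, 11 of 13 tested, while 2 rose (median −1.53). The list members Mrc1, Mertk and C1qa were under 10 CPM in every library, the control libraries included, as described with the third pattern below. Besides Csf1r and Cx3cr1, the lysozyme gene Lyz2 fell from 14553 ± 1066 to 2129 ± 23.1 CPM and Adgre1, which encodes the F4/80 antigen, from 331 ± 13.6 to 45.3 ± 6.12 CPM. The 2 that rose were the high-affinity IgG receptor gene Fcgr1 (60.3 ± 13.1 to 253 ± 18.8 CPM) and Sirpa (366 ± 86.7 to 805 ± 87.8 CPM). Camera called the list (adjusted p = 2.3e-07), with adjusted p = 0.33 with an estimated correlation. Csf1r and Lyz2 shared 14.3% and 15.4% of their 50-mers with the overlapping gene Hmgxb3 and with Lyz1. Phagocytic and scavenger receptors fell in 12 and rose in 2 of 15 cases (median −1.21), with the beta-glucan receptor gene Clec7a down 16.1-fold, Fcgr3 down 6.48-fold and Stab1 down 5.57-fold, and Itgav up by 1.16 ± 0.13. This list was called (camera adjusted p = 2.9e-05), with adjusted p = 0.32 with an estimated correlation. Complement genes fell in 9 and rose in 3 of 16 cases (median −0.83, and −0.47 with library size alone), and the receptor gene C5ar1 fell from 62.2 ± 14.7 to 12.6 ± 1.95 CPM. Among the lower ones, C1qa (38 counts to 0 over the libraries of a group), C1qb (69 to 2) and C1qc (77 to 0) were near the floor, and C1qa is also listed under macrophage identity. C3ar1 rose by 1.19 ± 0.16 (complement list, camera adjusted p = 0.0068, and adjusted p = 0.33 with an estimated correlation). The calls of the other 2 higher genes, Cfb and Cd59a, were lost with DESeq2 and without any 1 library (edgeR adjusted p = 0.10 to 0.24 for Cfb and 0.053 to 0.47 for Cd59a). Their log2 fold changes in these fits were 1.32 to 2.0 against 1.62 for Cfb and 0.94 to 1.96 against 1.54 for Cd59a. Cfb shared 73.0% of its 50-mers with a gene model. Genes of IL-4 type activation fell in 7 and rose in 1 of 10 cases (median −1.30), with the transglutaminase gene Tgm2 down 3.93-fold and the transcription factor gene Klf4 up 4.84-fold. Camera called that list as well (adjusted p = 0.0019), with adjusted p = 0.32 with an estimated correlation.

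Markers of other cell types moved with these genes. B cell markers fell in 4 of 5 tested cases (median −3.51), and Ighm, the constant region of the IgM heavy chain, fell from 233 ± 18.1 to 2.77 ± 0.169 CPM, while Cd79b went from 2.81 ± 0.645 to 0.243 ± 0.197 CPM and Ighd from 40 counts to 0, at least 17.6-fold lower. The B cell list was called by camera (adjusted p = 6.3e-04), with adjusted p = 0.32 with an estimated correlation, and its median, which is the value of Cd79b, was −2.86 without mimic replicate 1 and −4.68 without mimic replicate 2. Dendritic cell markers fell in 4 of 6 tested cases (median −1.13), among them Itgax 17.2-fold, Tcf4 3.68-fold and Siglech from 67 counts to 0, at least 29.4-fold (camera adjusted p = 0.013, and adjusted p = 0.33 with an estimated correlation). Without mimic replicate 1 the dendritic cell list was not called (adjusted p = 0.15), at a median of −1.20. Among its 4 lower members was Bst2, the interferon-stimulated gene whose call was lost or reversed in several fits. Of 6 tested neutrophil markers Lcn2 rose, and 4 fell, among them Prtn3, Csf3r (4.24-fold lower) and Elane (43 counts to 0, at least 18.9-fold lower), with camera adjusted p = 0.30. T and NK cell, mast cell, fibroblast and erythroid lists had 1 tested gene each: Lck rose from 4.70 ± 0.514 to 27.6 ± 0.916 CPM, Hdc from 0.249 ± 0.352 to 2.02 ± 0.007 CPM, and the other 2 did not pass. The log2 fold change of Hdc, 3.00, was 2.0 without control replicate 1 and 8.13 without control replicate 2.

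Glycolysis and hypoxia-target genes fell, 20 of 25, and 2 rose (median −1.91). The mitophagy receptor gene Bnip3 fell 15.5-fold, the aldolase gene Aldoc 13.8-fold (335 ± 9.26 to 24.2 ± 3.63 CPM) and the phosphofructokinase gene Pfkl 8.3-fold (497 ± 29.2 to 59.9 ± 2.39 CPM), while the glucose transporter gene Slc2a1 rose 1.4-fold and the hexokinase gene Hk3 1.35-fold, the latter with edgeR adjusted p = 0.057 without control replicate 1 (log2 fold change 0.40 against 0.43). Camera called the list (adjusted p = 4.9e-15), with adjusted p = 0.20 with an estimated correlation. Bnip3 shared 47.2% of its 50-mers with other genes, against 0% for Aldoc and 0.030% for Pfkl. Gapdh, a list member outside the rule for named genes and described below, shared 25.1%. Oxidative phosphorylation genes fell in 25 of 34 cases and none rose (27 fell adjusted over the list alone), with Ndufb10 down 3.58-fold, Ndufa1 3.8-fold and Atp5c1 2.73-fold (median −0.70, and −0.34 with library size alone). The list was called (camera adjusted p = 3.3e-05), with adjusted p = 0.33 with an estimated correlation. Transcripts of the mitochondrial genome fell in 12 of 14 cases (median −0.86, and −0.50 with library size alone), with mt-Rnr2 at 279 ± 13.1 against 113 ± 2.93 CPM and mt-Nd4 at 783 ± 3.96 against 377 ± 18 CPM (camera adjusted p = 0.015, and adjusted p = 0.44 with an estimated correlation). Of the 50-mers of mt-Nd4, 62.2% were shared with a gene model, against 1.04% for mt-Rnr2. Mitochondrial genes held 2.13% and 2.12% of counts in the control and 1.52% and 1.65% in the mimic libraries, and with gene-length offsets the list was not called (adjusted p = 0.44, median −0.23). Cytosolic ribosomal protein genes fell in 49 of 50 cases (median −1.40), with Rpl37 at 1295 ± 52.1 against 260 ± 19.3 CPM and Rps28 at 747 ± 37.5 against 95.3 ± 30.6 CPM. Camera called them (adjusted p = 5.4e-18), with adjusted p = 0.32 with an estimated correlation. The single ribosomal gene that rose, Rpl24, went from 2.17 ± 0.459 to 10.8 ± 3.57 CPM and shared 51.8% of its 50-mers with other genes.

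Lipid synthesis genes fell as well. Of 22 cholesterol synthesis genes 18 fell and 1 rose (median −0.92): Mvd, which encodes mevalonate diphosphate decarboxylase, fell 10.9-fold and Insig1 4.56-fold, and Hsd17b7 rose 2.51-fold. The list was called by camera (adjusted p = 2.9e-05), with adjusted p = 0.34 with an estimated correlation. In fatty acid synthesis and lipid storage 15 of 22 genes fell and 5 rose (median −0.88): the desaturase genes Scd2 and Scd1 fell 10.3-fold and 8.2-fold and the lipoprotein lipase gene Lpl 7.56-fold, while Plin2, which encodes a coat protein of lipid droplets, rose from 240 ± 57.3 to 1729 ± 157 CPM. Dgat2, 1 of the 5 higher genes, lost its call without control replicate 1 (edgeR adjusted p = 0.053, log2 fold change 1.30, against 3.31 without control replicate 2). Camera called it (adjusted p = 0.0055), with adjusted p = 0.32 with an estimated correlation. Lysosomal genes fell in 22 and rose in 7 of 35 cases (24 and 8 adjusted over the list alone, median −0.59), with the protease gene Lgmn down 5.81-fold and the transcription factor gene Tfeb 5.62-fold, and Atp6v1h up by 1.02 ± 0.13. That list was called too (camera adjusted p = 0.0019), with adjusted p = 0.34 with an estimated correlation. Cholesterol efflux and LXR targets did not stand apart (4 higher and 6 lower of 14, camera adjusted p = 0.59), although the endosomal cholesterol transporter gene Npc1 rose 5.21-fold and the phospholipid transfer protein gene Pltp fell 4.55-fold. With library size alone the medians were −0.55 for cholesterol synthesis, −0.52 for fatty acid synthesis and −0.22 for lysosomal genes.

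**Figure D3:**
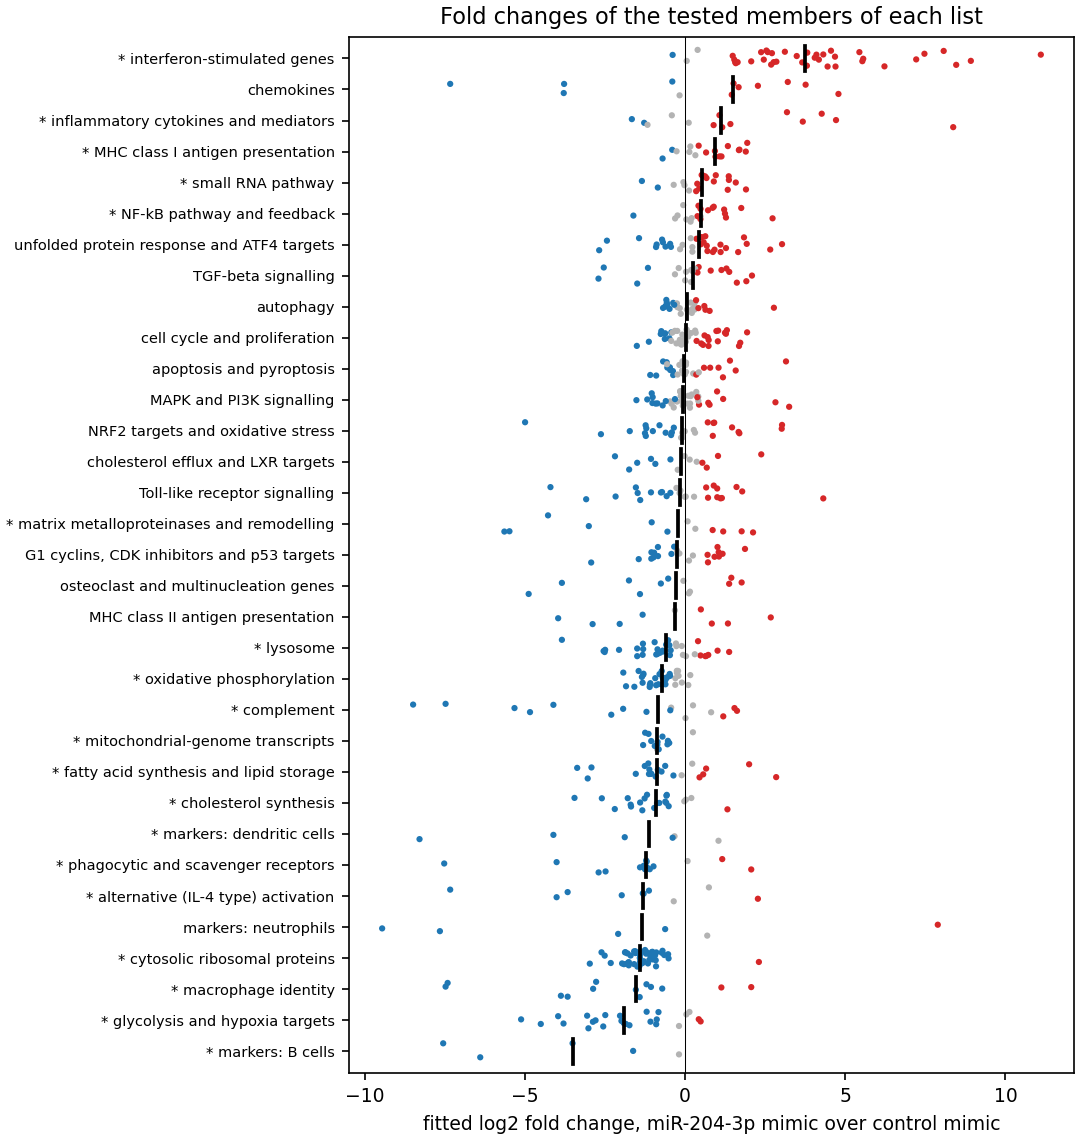
Fitted log2 fold changes (x axis, miR-204-3p mimic over control mimic) of the tested members of the 33 lists with at least 5 tested genes (y axis), each point a gene, red for higher, blue for lower and grey for not past the threshold, with a black bar at the list median and an asterisk where camera called the list with the preset correlation. Medians run from −3.51 for B cell markers to 3.73 for interferon-stimulated genes, and fitted values of genes with 0 counts in a group depend on the prior count.

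Genes of the small RNA pathway were mostly higher, 14 of 20, and 2 were lower (median 0.54, and 0.90 with library size alone). Ago2, which encodes the Argonaute that cleaves targets of small RNAs, rose from 161 ± 12.9 to 407 ± 45.1 CPM, Tnrc6c and Tnrc6a, which encode GW182 partners of Argonaute, by 1.90 ± 0.14 and 1.59 ± 0.14 on the log2 scale, and Dicer1, which encodes the enzyme that cuts microRNA precursors, by 0.90 ± 0.13. Prkra and Cnot8 fell by 1.34 and 0.85. Camera called this list (adjusted p = 0.021), with adjusted p = 0.51 with an estimated correlation, and not without control replicate 2 (adjusted p = 0.054, median 0.58) or with gene-length offsets (adjusted p = 0.17, median 0.42). Trpm3, the host gene of miR-204, had 7, 9, 7 and 4 counts in the 4 libraries, and Gnb4 had 0, 2, 11 and 7, so neither was tested.

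Other lists went both ways. Matrix metalloproteinase and remodelling genes fell in 6 and rose in 4 of 12 cases. The heparanase gene Hpse fell 44.6-fold and the urokinase gene Plau 19.3-fold, and the urokinase receptor gene Plaur rose 4.36-fold and the osteopontin gene Spp1 2.29-fold. Camera called them lower (adjusted p = 0.034), with adjusted p = 0.33 with an estimated correlation, but not without mimic replicate 1 (adjusted p = 0.49, median −0.29) or mimic replicate 2 (adjusted p = 0.32, median −0.21), and their median of −0.23 became 0.13 with library size alone. Unfolded protein response and ATF4 target genes were higher in 17 and lower in 10 of 32 cases (camera adjusted p = 0.12), with Ddit3 up by 2.66 ± 0.14 and the cystine transporter gene Slc7a11 by 3.03 ± 0.16, and Ddit4 down by 2.68. Among NRF2 targets and oxidative stress genes 9 rose and 13 fell of 28 (11 and 13 adjusted over the list alone, camera adjusted p = 0.62), and the NADPH oxidase gene Cybb fell from 1360 ± 29.0 to 42.8 ± 1.04 CPM and Ncf1 6.16-fold, while Me1 rose 8.1-fold. Cell cycle genes rose in 16 and fell in 9 of 42 cases (camera adjusted p = 0.30), with the replication genes Mcm2 and Mcm4 up 3.22-fold and 2.38-fold and the proliferation marker Mki67 down 2.18-fold. G1 cyclin, CDK inhibitor and p53 target genes were higher in 8 and lower in 10 of 23 cases (camera adjusted p = 0.68), with Mdm2 up 2.25-fold, Sesn1 down 7.6-fold and Ccnd1 down 2.07-fold. Apoptosis and pyroptosis genes were higher in 8 and lower in 9 of 29 cases (camera adjusted p = 0.52), with the inflammatory caspase genes Casp4 and Casp1 up 8.89-fold and 2.07-fold and Mcl1 down 2.12-fold. In autophagy 6 rose and 9 fell of 27 (camera adjusted p = 0.68), and the receptor gene Sqstm1 rose from 658 ± 88.4 to 4505 ± 116 CPM. TGF-beta signalling genes rose in 9 and fell in 4 of 21 cases (camera adjusted p = 0.72), with Tgfb3 down 6.49-fold and Tgfbr2 5.79-fold. Osteoclast genes fell in 6 and rose in 3 of 12 cases (camera adjusted p = 0.21), with Ocstamp at 23.7 ± 4.93 against 0.791 ± 0.501 CPM (log2 fold change −4.88, and −5.74 without mimic replicate 1). Of the 3 higher osteoclast genes, Ctsk lost its call without any 1 library (edgeR adjusted p = 0.12 to 0.19), at log2 fold changes of 1.28 to 1.46 against 1.38. Mmp9, also a remodelling gene, lost it in 3 of 4 such fits (edgeR adjusted p = 0.079 to 0.24), at 1.15 to 1.83 against 1.77 and at 2.87 without control replicate 1, and both calls were lost with DESeq2. MAPK and PI3K genes rose in 8 and fell in 10 of 37 cases (8 and 9 adjusted over the list alone, camera adjusted p = 0.94), with Dusp4 up 7.08-fold. The medians of 9 of the 33 lists changed sign with library size alone: Toll-like receptor, MHC class II, cholesterol efflux, G1 and p53, apoptosis, NRF2, remodelling, osteoclast, and MAPK and PI3K genes.

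Transcripts with a miR-204-3p seed site were not lower as a set. Among 11267 protein-coding genes with an annotated 3′ UTR, 2536 carried the 7mer-m8 site TTCCCAG, and their median log2 fold change was 0.13 against 0.02 for the other 8731, a difference of 0.11 (95% bootstrap interval over genes 0.07 to 0.16). The difference ranked 252 from the lowest among the site and 419 control 7-mers, whose median difference was 0.10. For the 703 genes with the 8mer TTCCCAGA the difference was 0.03 (interval −0.05 to 0.11), at the 19.5th percentile of its controls. The 8mer controls spread widely, with a 5th percentile of −0.12, against 0.007 for the 7mer controls. A small fall of the genes with an 8mer could therefore be missed. Sites of the 7mer-m8 or 7mer-A1 type occurred in 26.4% of lower, 32.8% of higher and 29.9% of other genes, whose median 3′ UTR lengths were 876.5 (lower), 1382 (higher) and 1154 bases (other). The 7mer-m8 site alone occurred in 19.3% of lower and 24.8% of higher genes. The ratio of these shares, 0.778, was close to the median of 0.765 for control 7-mers.

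Some single genes with an 8mer were much lower. Those named here were picked as lower and of lowest p, so the size of their falls is no sign of an effect of the site. The 5 with the lowest p among the 197 lower genes with an 8mer were Csf1r, Igf1, Ak4, AB124611 and Gas7, each with 1 such site in the 3′ UTR of the longest annotated form. In mm10 the sites lie at chromosome 18, 61130641 to 61130648, for Csf1r, and chromosome 10, 87933324 to 87933331, for Igf1. That of Ak4 lies at chromosome 4, 101466208 to 101466215. Those of AB124611 and Gas7 lie at chromosome 9, 21545034 to 21545041, and chromosome 11, 67687429 to 67687436, and all 5 genes are on the plus strand. Ak4, an adenylate kinase gene, went from 115 ± 9.8 to 9.25 ± 0.651 CPM, AB124611 from 585 ± 57.0 to 77.7 ± 5.11 CPM and Gas7 from 282 ± 62.2 to 28.0 ± 0.0725 CPM. An 8mer was present in 5.91% of lower and 6.59% of higher genes.

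**Figure D4:**
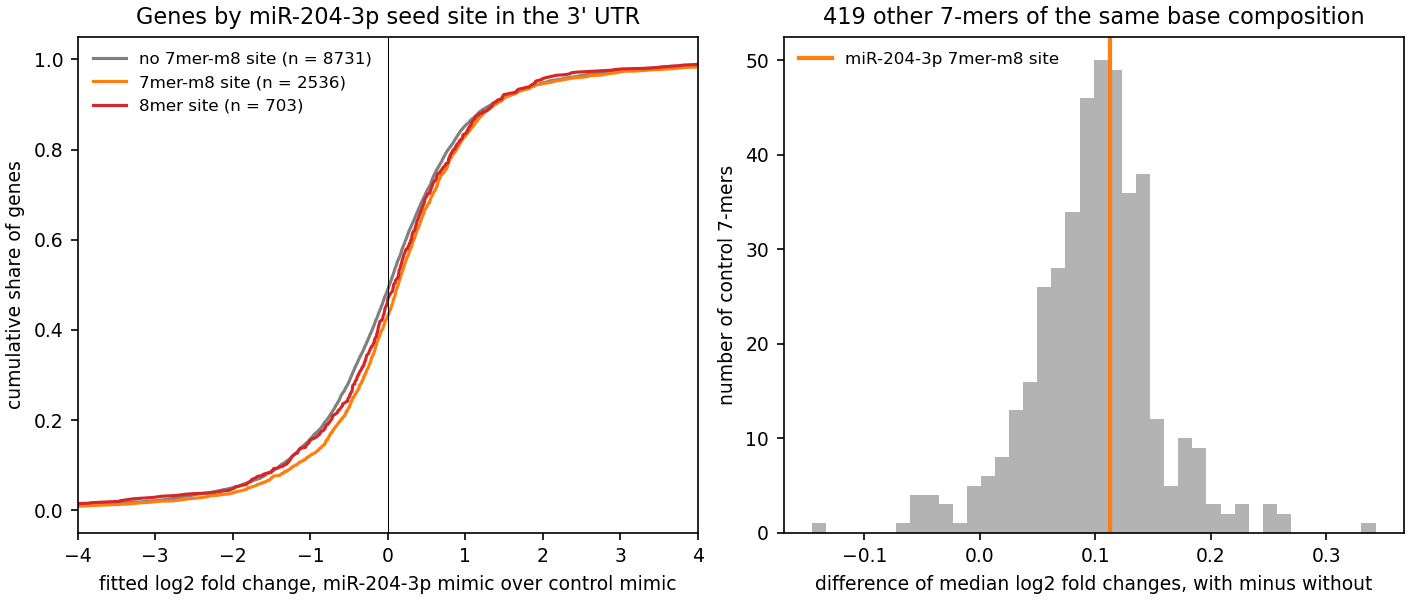
Left, cumulative share of genes (y axis) by fitted log2 fold change (x axis) for 8731 genes without and 2536 genes with a 7mer-m8 site for miR-204-3p in the 3′ UTR and for the 703 genes with an 8mer. Right, histogram of the difference of medians for 419 control 7-mers (x axis, log2; y axis, number of 7-mers) with the line at 0.11 for the miR-204-3p site, near the control median of 0.10.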

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

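Gene-length offsets, library size alone for the lists and the 8mer within length deciles were chosen after the results were seen, and all other settings before. The number of changed genes (8022) ranged from 6396 (adjusted p of 0.01) to 8664 (library size alone), and from 7225 to 7683 with 1 library left out, apart from glmTreat against 1.5-fold, which gave 4470 (2213 higher, 2257 lower) because it sets a minimum fold. Library size alone gave 2513 lower genes and shared 6614 calls with the TMM scaling, all in the same direction. DESeq2 called 7082 genes and shared 6945. The replicate numbers showed little sign of pairing: differences between replicates correlated across genes at r = 0.024 between groups, and at 0.099 over the 9046 genes at 10 CPM or more. Gapdh, described below, was nevertheless far higher in replicate 1 of both groups. The replicate block gave 8070 genes and 19 lists, but ended the calls of Il27 (−1.31, edgeR adjusted p = 0.052), Cfb, Cd59a and Ctsk. Lists called by camera numbered 19, against 24 by fry and 0 by camera with an estimated correlation, where the lowest adjusted p was 0.12. With the few residual degrees of freedom of 4 libraries, that version could hardly call a list. Of 196 genes recomputed, 8 lost their call with library size alone, 26 with glmTreat, 6 with DESeq2 and 6 to 8 with 1 library left out, and where an arm was left with 1 library it was assumed to vary like the other. Bst2 reversed with gene-length offsets (0.12, adjusted p = 0.43); the cause was not tested. The seed-site difference of 0.11 was 0.10 to 0.13 with 1 library left out and −0.0013, at the 48.7th percentile of its controls, within deciles of 3′ UTR length, whose construction removes the trend with length. The 8mer difference of 0.03 was −0.077 within these deciles, at the 20.2nd percentile of its controls. The seed site of the opposite arm, miR-204-5p, gave 0.056, below all 34 of its controls; the cause was not tested. FPKM was not run, and genes near 3 counts were limited by depth.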

Other observations

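The tests of the 3 patterns weighed here, the genes Csf1, Myc, Trem2, Cd33, P2ry6, Gpr183, Irf8, Cebpa, Hspa8, Hsp90ab1 and Gapdh, and the sets of macrophage and interferon transcripts were chosen after the results were seen.

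Csf1, which encodes macrophage colony-stimulating factor, the ligand of Csf1r, rose from 6.63 ± 0.53 to 140 ± 16.3 CPM (SD, 2 libraries each), opposite to its receptor. The surface receptor gene Trem2 fell from 867 ± 21.7 to 56.4 ± 1.03 CPM, that of the sialic acid-binding receptor Cd33 from 728 ± 39.6 to 39.3 ± 3.39 CPM, that of the nucleotide receptor P2ry6 from 109 ± 2.99 to 3.72 ± 0.402 CPM and Gpr183 from 113 ± 9.86 to 2.97 ± 0.59 CPM. The myeloid transcription factor genes Irf8 and Cebpa fell by 2.24 and 2.71 on the log2 scale, and Myc rose by 4.17. The chaperone genes Hspa8 and Hsp90ab1 fell by 2.45 and 1.69, and Hspa8 shared 39.4% of its 50-mers with other genes. Each of these 10 genes kept its call under all 14 alternatives run, which include DESeq2.

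Classes of transcripts differed too. Of 708 tested lincRNA, antisense and unclassified (TEC) genes 265 rose and 105 fell, and of 708 tested processed pseudogenes 67 rose and 350 fell. Processed pseudogenes held 2.65% and 2.62% of counts in the control and 1.62% and 1.64% in the mimic libraries. Gapdh, often used as a reference gene, had 7800 and 236 counts in the control and 1676 and 143 in the mimic libraries, which is a 32.2-fold and an 11.2-fold difference in CPM within the groups. It shared 25.1% of its 50-mers with 223 other genes and is also a member of the glycolysis and hypoxia list. How reads that fit several genes were counted was not given in the sources used here. These values are therefore uncertain, as are those of processed pseudogenes, ribosomal protein genes and glycolysis list members with copies, such as Bnip3.

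The first pattern is that most tested genes changed, 8022 of 13186. The other splits of the 4 libraries into 2 pairs gave 0 genes each, too few splits for a share under 0.05. They pair a control with a mimic library, so the group difference counts as spread within pairs, and the result says little on false calls. Direct repression of the lower genes through 7mer sites in the longest annotated 3′ UTR cannot be the whole cause, since 26.4% carried one. Such sites were no more frequent there than in higher (32.8%) or other genes (29.9%), so the share is not a count of direct targets. It leaves out sites with the 6mer TCCCAG alone and sites in coding sequence, so repression through those was not excluded. The 6mer, alone or within a 7mer, occurred in 5394 of 11267 3′ UTRs. Gene length bias cannot be the whole cause either, since 7990 genes passed after gene-length offsets. Cultures that differed before transfection cannot be told apart from an effect of the mimic: the highest correlation between groups was r = 0.885, and the group is the sole label that separates the libraries. An effect of the mimic that spreads through regulators such as Csf1r may be a biological explanation and stays untested.

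The second pattern is the rise of 37 of 40 interferon-stimulated genes. Neutrophils, dendritic cells or B cells in the mimic cultures do not account for it, because each of these marker lists had at most 1 higher member and at least 3 lower ones besides Bst2, a dendritic cell marker that is also interferon-stimulated and whose call did not hold in several fits. T and NK cells, mast cells, fibroblasts or erythroid cells do not account for it either, since the highest of their 4 list medians in the mimic libraries was 0.026 CPM, against a median rise of 38.0 CPM in interferon-stimulated genes, with Cd3e and Col3a1 at 0 counts and only Lck above 10 CPM among 46 markers. Interferon made by the mimic cultures may be the cause. The 20 interferon genes examined, however, had 2 counts over both mimic libraries, all from Ifna2. No earlier time was sampled, so interferon cannot be told apart from a direct response to the RNA duplex of the miR-204-3p mimic. The control cultures received a mimic too, so a response of equal size to both mimics would not appear in this comparison. A direct response could explain the rise only if it was stronger to the miR-204-3p mimic. Cultures that differed before transfection, as for the first pattern, cannot be told apart from these explanations. The control mimic has no group without transfection beside it, which leaves the response to transfection itself unmeasured.

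The third pattern is that 11 of 12 transcripts usually abundant in bone marrow-derived macrophages were under 10 CPM in all 4 libraries: Mrc1, Mertk, C1qa, C1qb, C1qc, Apoe, Ms4a7, Maf, Pycard, H2-Aa and H2-Ab1, with Apoe the highest at 6.97 CPM. The exception was Cd74, at 508 to 756 CPM, and Lyz2, Cd68 and Gpnmb were above 400 CPM in each library. Reads lost to near-identical copies do not account for the low values, since at most 11.7% of the 50-mers of any of the 11 genes were shared with other genes. An established macrophage line is a candidate explanation, since the RAW line is known to lack Pycard, which had 6 counts in total, but primary cells with the same processing were not analysed here, so it cannot be told apart from a particular state of primary cultures. No biological explanation was tested for this pattern, because the design gives no group that differs in it.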
